A study of Mus musculus with 25 samples.

How the data were processed

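Total RNA was measured by RNA sequencing in 25 libraries of mouse CD4+ T cells, per the labels. Of these, 9 came from the spleens of mice infected with the parasite Leishmania donovani, and 16 came from naive cells before and after 18 h of culture under conditions that favour the Th1 fate. The genotypes were C57BL/6 wild type (WT) and C57BL/6 miR-132 -/- (KO), per the labels. KO animals were taken to lack miR-212 as well, which the sample labels do not state. RNA was extracted with QIAzol and miRNeasy kits, per the labels' protocols. The library kit, its strand setting and the read numbers were not given in the sources used here.

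The deposited values were FPKM (fragments scaled to locus length and library size), one value for each assembled locus and library, per the file headers. Reads were trimmed with cutadapt 1.8.3, aligned with HISAT2 2.0.5 to GRCm38.p4, assembled with Cufflinks and normalized with Cuffnorm, per the submitters' processing notes. Versions of the last pair of tools and the scaling method were not given in the sources used here. The infected and the in vitro libraries were in 2 separate tables that the authors normalized separately. Every test therefore stayed within a table.

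A table held 60802 loci for infected cells and 59884 for cells in vitro. A locus could carry several gene names, and many carried none. Loci were placed in a strand order in each table, and the names of silent loci showed which part of the order stood for which strand. For genes with signal on both strands, a median of 99.5% of it (infected) and 99.2% (in vitro) lay on loci of the strand opposite to the gene, so that strand was read as the gene's own. Names were kept on loci of that strand, 8896 and 8497 of those tested. A locus without such a name took the protein-coding gene of GENCODE M21 that alone overlapped it on that strand (2336 and 2576 loci), or that alone overlapped a gene named there in the other direction (213 and 352). The position rule gave the named gene for 6941 of 6941 and 6146 of 6148 loci where both could be read, and the other rule for 983 of 1026 and 1024 of 1124. Those loci already carried a name on that strand, so the position rule could hardly have given another gene. The accuracy of either rule on loci without such a name was not tested. No gene was given to 3282 and 4542 tested loci. Ssbp3, Vcam1, Il2, Bcat1, Eif5a, Foxp3, Il16, Gbp2, Ccnd3, Hk2, Zap70, Itpkb, Txnip, Cd44, Hat1, Rps27, Mrpl58 and Il4ra were identified by position, as were Tbx21 and Pes1 in the infected table. Loci of chromosome 8 between 119.9 and 124.3 Mb were not analysed here.

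Depth could not be read as a total, because FPKM hold no read counts. Loci with low values move in steps that depend on depth, and the steps gave relative depths. Against the first library of its table, depth ranged from 0.629 (infected KO 4) to 1.89 (infected KO 1) times, and from 0.914 (18 h WT 2) to 6.41 times in vitro. Libraries are numbered by their order of deposit within a group.

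Loci with an FPKM of at least 1 in at least 4 libraries of their table were tested: 14819 (24.4%) infected and 16185 (27.0%) in vitro. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over the loci tested and a threshold of 0.05. Fold changes are on that log2(FPKM + 1) scale, which understates the change of genes with low values. The 9 infected libraries were fitted alone. The 16 in vitro libraries were fitted as 4 group means, from which both genotype effects, both effects of stimulation and the interaction (KO effect at 18 h minus KO effect in naive cells) were taken. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries only.

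A set of 32 gene lists was tested with camera at a preset correlation of 0.01, on lists with at least 5 measured members, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The cytosolic ribosomal protein list was chosen because the published study of these mice is known to concern those genes, so it is not independent evidence. Groups, comparisons, tests, lists, the gene-naming rule and the alternatives called planned were fixed before the data were examined. The rule named, per comparison, the 5 largest rises and 5 largest falls among called genes whose groups did not overlap, leaving out predicted genes, pseudogenes and receptor segments. It also named up to 2 rises and 2 falls from each list, and in every case Ep300, Ifng, Il10, Il2, Tbx21, Mir132 and Mir212. Which list members the text leaves out was settled after their values were seen, while the alternatives were computed for all of them. Genes named outside the rule are said to be so.

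Matches to the seed of miR-132 and miR-212 (8mer GACTGTTA, 7mer-m8 GACTGTT, 6mer ACTGTT) were sought in the longest annotated 3' UTR of 21130 genes. The median fold change of genes with a site, less that of genes without a 6mer, was set against 10000 random lists matched on expression and UTR length. The way those lists were drawn was changed after a check on simulated data, and after a first p-value had been seen, because the first version gave too many low p-values. With the final version, 6 of 100 simulated sets of infected fold changes without a shift fell below 0.05, and 12 of 100 for 8mer sites alone. Those fold changes were drawn independently for each gene. The check therefore does not cover correlation between genes, which the splits of the libraries keep.

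The model was tested on simulated data with 200 changed genes. Among loci of the infected table it found 13.4% of changes of 0.5 (log2), 38.8% of changes of 1 and 62.1% of changes of 2, with 3 calls among unchanged loci. For naive cells these were 17.9%, 59.7% and 78.8%, and for cells at 18 h 14.9%, 59.7% and 84.8%. For the interaction they were 4.48%, 25.4% and 63.6%.

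Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling of each library to the same sum, median centring, quantile normalization, library weights, robust eBayes, a fit of the 2 groups compared only and each library left out. Added after the data were seen were 1 locus per gene, a rescaling without loci above 100000 FPKM, leaving out 3 in vitro libraries at once, a block for the order of deposit, and every list under each scaling. At most 100 other splits of the libraries were drawn per result. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table (1.17.8), were used for the rest.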

Results

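RNA of CD4+ T cells was sequenced from C57BL/6 mice that were wild type (WT) or labelled miR-132 -/- (KO). The KO mice were taken to lack miR-132 and miR-212, a pair of related small RNAs that repress messenger RNAs with matching sites. One table held 9 libraries of splenic CD4+ T cells from mice infected with Leishmania donovani, a parasite that persists in spleen and liver (4 WT, 5 KO). The other held 16 libraries of naive CD4+ T cells and of cells after 18 h of Th1 culture (4 per genotype and state). That culture used antibodies to CD3 (10 µg/ml, on the plate) and CD28 (2 µg/ml) with IL-12 (15 ng/ml) and antibody to IL-4 (5 µg/ml), per the labels. The protocols also give 4 h of PMA (500 ng/ml) and ionomycin (1 µg/ml) for cells from infected spleens, without saying whether the sequenced cells received it.

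Summed FPKM ranged from 389446 (18 h WT 2) to 8331600 (naive KO 1), where the Kif5c locus alone was listed at 7620000. The 10 highest loci, among them the small RNAs Rn7sk and Rpph1, held 33.4% to 95.6% of the sum in vitro and 45.1% to 74.9% in infected cells. Loci above 0 were fewest in 18 h WT 2 (14022), which also had the lowest relative depth in vitro.

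The loci of the deleted genes themselves gave no check of the labels. The loci of Mir132 (chromosome 11, 75173682 to 75173747, GRCm38) and Mir212 (75173388 to 75173478) were listed at 0 in all 25 libraries. Mature microRNAs are shorter than the fragments of most total RNA libraries. The surrounding locus named after Dph1 and Ovca2 (75172560 to 75191241) was listed in infected WT at 3.41, 3.21, 2.66 and 2.51 FPKM and in infected KO at 0.581, 0.462, 0.166, 0.574 and 0.492 (log2 fold change -1.44, adjusted p 0.0371). In naive cells it stood at 0.228, 0.591, 0.689 and 0.147 in WT against 0, 0, 0.160 and 0.0950 in KO. At 18 h it stood at 0.306, 0, 0.383 and 0.555 in WT and at 0.219, 0.289, 0.127 and 0.0709 in KO. By the strand rule used here, the signal of this locus lay on the strand of Mir132 and Mir212. In infected cells every KO value was below every WT value, so there the locus separated the labelled groups. In vitro the groups overlapped near 0.

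In infected mice, the question was how the lack of the microRNAs alters CD4+ T cells during a lasting infection. Genes that rose in KO cells included those for the ribosomal proteins Fau and Rpl12, and Uqcrq and Uqcrc2, which encode parts of respiratory complex III. The histone gene Hist1h3f, which packs new DNA, the DNA-binding cofactor Ssbp3 and the RNase P subunit gene Rpp25l also rose. Genes that fell included Vcam1, an adhesion molecule of vessel and stromal cells, and Atg16l1, which forms autophagosomes. Genes of T cell receptor alpha variable segments (Trav) from a single stretch of chromosome 14 were high in KO cells and near 0 in WT cells. Neither Ifng and Tbx21, the cytokine and master regulator of Th1 cells, nor Il10, the cytokine that restrains them, passed the test.

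Among 14819 loci, 79 passed (66 higher and 13 lower in KO), which correspond to 63 genes (57 higher, 6 lower). They included 17 Trav genes, 6 ribosomal protein pseudogenes, 19 predicted genes and 7 loci without a gene. Rescaled to equal sums, 46 loci passed, 25 higher and 21 lower. The count fell to 36 without infected WT 2, 39 without WT 4, 45 without KO 5, 50 without WT 3 and 52 without KO 1 or without KO 3. At an unadjusted p below 0.05 there were 1621 loci, against 741 expected by chance.

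Hist1h3f (chromosome 13, 23544052 to 23545312) stood at 89.8 ± 14 FPKM in WT (mean ± SD, n = 4) and 367 ± 112 in KO (n = 5), a log2 fold change of 1.98 (SE 0.21, adjusted p 0.00226). Ssbp3 rose from 5.72 ± 0.381 to 17.5 ± 4.71 (1.43, adjusted p 0.00652), Uqcrq from 33.8 ± 2.29 to 77.3 ± 16 (1.15, 0.00887) and Uqcrc2 from 101 ± 18.5 to 195 ± 20.5 (0.95, 0.0105). Rps3a2, a second gene for the ribosomal protein S3a, rose by 1.64 (0.0325), Rpp25l by 1.19 (0.0310), Fau by 1.02 (0.0309) and Rpl12 by 0.99 (0.0465). Atg16l1 fell from 135 ± 17.5 to 82.1 ± 12.5 (-0.72, 0.0465). Histone and ribosomal protein genes have near-identical copies, so their reads could not be assigned to one copy with certainty.

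Vcam1 was listed in WT at 3.34, 2.46, 7.77 and 7.29 and at 0 in all 5 KO libraries (adjusted p 0.00953). The troponin gene Tnnt3 was listed at 2.69, 5.53, 2.11 and 6.15 in WT and above 0 in KO only in KO 3, at 0.955 (0.0456). Ica1, of secretory vesicles, was listed at 2.61, 5.89, 4.07 and 1.31 in WT (0.0358) and the chaperone gene Clgn at 2.85, 1.70, 1.96 and 2.21 (0.0264), both at 0 in KO. Every infected KO library had fewer loci above 0 (17108 to 19527) than every WT library (20078 to 21265). The 13 falls were 6 with a pseudocount of 0.1, 7 with a stricter filter and 3 without a filter. The calls of Hist1h3f, Ssbp3, Uqcrq, Uqcrc2 and Vcam1 held with each library left out. Those of the others did not: the highest adjusted p was 0.18 for Rpl12, 0.172 for Tnnt3, and 0.118 for both Fau and Rpp25l, all without infected WT 2. It was 0.157 for Atg16l1, 0.0896 for Rps3a2 and 0.0818 for Clgn without WT 4, and 0.121 for Ica1 without WT 3.

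Il10 was 107 ± 4.72 FPKM in WT and 135 ± 32.9 in KO (log2 fold change 0.30, SE 0.16, adjusted p 0.524). Ifng was 2830 ± 213 and 2494 ± 573 (-0.21, 0.739), Tbx21 32.6 ± 1.81 and 28.0 ± 3.04 (-0.22, 0.471), and Il2, the T cell growth factor, 102 ± 26.7 and 148 ± 49.3 (0.51, 0.472). Ep300, a histone acetyltransferase gene with a described site for miR-132, was 22.9 ± 0.447 and 21.8 ± 1.90 (-0.07, 0.836).

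The 17 Trav loci that passed lay between 53351028 and 53704514 on chromosome 14, a stretch of 353 kb whose ends they set. It held 19 of the tested Trav loci, and 29 lay outside it, of which 0 were higher and 5 lower in every KO than in every WT library, where chance gives 0.794% either way (median -0.79). In 13 of the 19, all 4 WT libraries were listed at 0, and the highest WT value in the stretch was 1.76 FPKM. Its share of all Trav signal was 0.289%, 0.564%, 0.616% and 0.232% in infected WT and 57.4% to 76.2% in infected KO. In naive cells it was 31.4%, 54.3%, 13.9% and 33.7% in WT and 50.5% to 57.5% in KO, and at 18 h 32.9%, 52.1%, 2.87% and 37.6% in WT and 51.7% to 58.0% in KO.

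**Figure D1:**
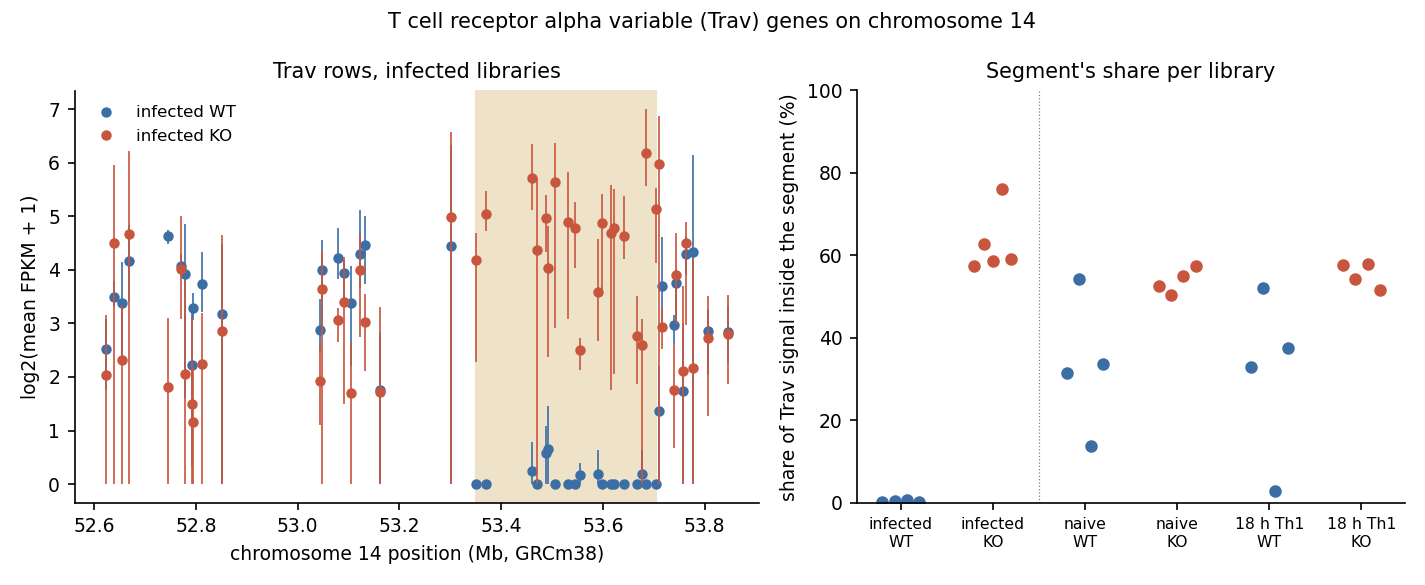
Left: log2(mean FPKM + 1) of Trav loci by position on chromosome 14 (Mb), infected WT and KO, with lines from the lowest to the highest library and the 353 kb stretch shaded. Right: the stretch's share (%) of Trav signal in each of the 25 libraries, below 0.62% in all 4 infected WT and at least 57.4% in all infected KO.

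Cytosolic ribosomal protein genes were the lead list, and the study's known interest in them makes their count no independent evidence. Of 73 measured, 58 were higher and 15 lower in infected KO, with a median of 0.35; 2 passed over all loci, and 27 higher and 7 lower when adjusted over the list alone. Camera at the preset correlation gave an adjusted p of 1.02e-07, and with the estimated correlation 0.589. Rescaled to equal sums the median was -0.16, where the median of all loci moved by -0.43, and under quantile normalization it was 0.10.

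**Figure D2:**
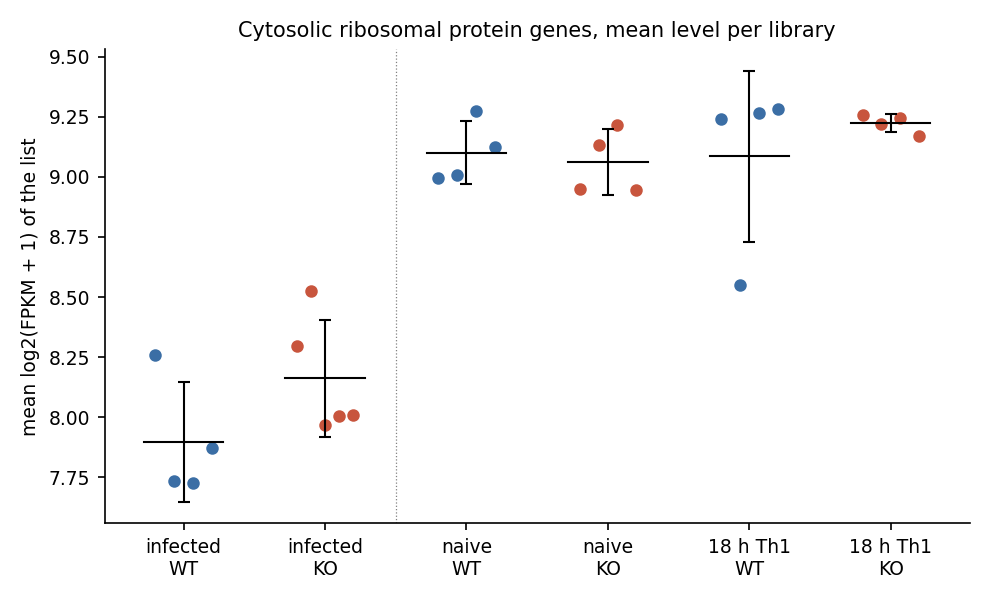
Mean log2(FPKM + 1) of the cytosolic ribosomal protein list in each of the 25 libraries, with group mean and SD; the 2 tables were normalized separately. Levels were 7.73 to 8.26 in infected WT and 7.97 to 8.53 in infected KO, and 18 h WT 2 stood at 8.55.

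Other groups of genes that supply growth were higher in infected KO by camera at the preset correlation. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.442. Ribosome biogenesis genes such as Pes1, Nop58 and Ddx21 had a median of 0.33, with 29 of 30 higher (12 higher when adjusted over the list alone, adjusted p 4.10e-10). Translation factors such as Eif3l and Eef1g had a median of 0.25 with 32 of 33 higher (11 alone, 3.60e-09). Subunits of oxidative phosphorylation had 0.23 (8 alone, 0.00104), and proteasome subunits 0.17, with 4 higher and 1 lower alone (0.00104). Mitochondrial ribosomal proteins (0.15, 0 alone, 0.0201), glycolysis genes (0.21, 0.012) and amino acid and one-carbon genes (0.24, with Mthfd1 alone, 0.0132) also passed. The Th1 program list was lower (-0.21, 23 of 27 lower, 0.0133), as were cell cycle genes (-0.15, 27 of 34 lower, 0.0209), with 0 members of either past the test alone. Infected KO 1 and KO 2 had the lowest mean log2 levels for both (5.44 and 5.22 for Th1, 3.03 and 2.93 for cell cycle), while KO 3 to KO 5 (5.69 to 5.85 and 3.25 to 3.39) lay at the level of WT (5.69 to 5.78 and 3.24 to 3.42). The same 2 libraries were highest for translation factors (6.58 and 6.76), where WT 1 (6.44) lay above KO 3 (6.42) and KO 4 (6.41). Ribosome biogenesis levels did not overlap (5.40 to 5.59 in WT, 5.66 to 6.02 in KO). Fry passed proteasome subunits only (0.0372). Rescaled to equal sums, 8 of the 10 lists that passed, ribosomal proteins included, changed sign, to medians between -0.16 and -0.33 that stayed above the -0.43 by which all loci moved, and none of the 10 passed camera.

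The remaining lists did not pass in infected cells. Medians and adjusted p were 0.32 and 0.121 for Th2, -0.26 and 0.163 for Th17, 0.14 and 0.432 for regulatory, 0.10 and 0.469 for follicular helper, and 0.09 and 0.306 for naive and quiescent T cell genes. They were 0.07 and 0.368 for activation genes, where Cd44 and Tfrc were higher and Batf lower alone, and -0.07 and 0.368 for interferon-stimulated genes. T cell receptor signalling had 0.08 and 0.368, described targets of miR-132 and miR-212 -0.02 and 0.844, and genes near the deleted locus 0.11 and 0.368. Co-inhibitory receptors (-0.01, 0.891) and cytokines (-0.01, 0.917, with Csf1 lower alone) had means of 0.05, against their medians. Marker genes of other cells had 0.15 and 0.433 for B cells, 0.48 and 0.173 for erythroid cells (5 of 5 higher, Tfrc alone), and 0.04 and 0.836 for monocytes, whose mean was -0.08. Too few members were measured for a test of plasma cell (-0.30), neutrophil (0.19), dendritic cell (0.30), NK and CD8 (0.19), platelet (-0.44), mitochondrially encoded (-0.21) and sex-linked genes (Xist, -0.10).

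In naive cells, the question was whether genotype mattered before stimulation. S100a8, which encodes a calcium-binding protein abundant in neutrophils, was listed in KO cells alone. Ddit4, a stress-induced brake on the mTOR growth pathway, and Ide, the insulin-degrading protease, rose in KO. The list of T cell activation genes, which holds the transcription factor genes Junb and Nr4a3, was lower by camera at the preset correlation. With an estimated correlation it did not pass (adjusted p 0.988), and 0 members passed.

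Of 16185 loci, 6 passed (5 higher, 1 lower), and 1261 had an unadjusted p below 0.05 against 809 expected. Without naive KO 3 the count was 12, with library weights 2 and in a fit of the 2 groups alone 1. Under quantile normalization it was 16 (11 higher, 5 lower), and rescaled to equal sums it was 5 (2 higher, 3 lower) as all loci moved by -0.53. S100a8 was listed at 0 in all 4 WT libraries and at 11.5, 9.19, 9.01 and 36.8 FPKM in KO (adjusted p 0.00366). Ddit4 (chromosome 10) was 15.6 ± 3.25 in WT and 32.6 ± 4.62 in KO, n = 4 each (log2 fold change 1.03, SE 0.16, adjusted p 0.0341). Ide (chromosome 19, 37268743 to 37337852) was 6.63 ± 0.608 and 12.7 ± 2.33 (0.83, 0.0374). S100a8 held with each library left out, whereas Ddit4 and Ide each reached 0.196 without naive KO 2.

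The other 3 loci were outside the naming rule and are named after their values were seen. Tmem181b-ps, a pseudogene on chromosome 17, was listed in WT at 0, 0, 0.118 and 0.0853 and in KO at 6.62, 10.4, 5.78 and 7.28 (1.75e-07). A locus without a gene name on chromosome 19 (37235124 to 37238454) was at 0, 0.115, 0 and 0.0894 in WT and at 2.91, 1.75, 1.57 and 3.01 in KO (0.00383). A second locus of Far1, for a fatty acyl reductase, was lower in KO (-1.34, 0.00979). Ifng (-0.30, 0.943), Tbx21 (-0.20, 0.913), Ep300 (-0.01, 0.993) and Il2 (0.02, 0.994) did not pass. Il10 had no tested locus of its own in vitro.

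Activation genes were the only list of 21 tested to pass in naive cells at the preset correlation (median -0.11, 21 of 27 lower, adjusted p 0.0214), with 0 members past the test alone. With an estimated correlation 0 lists passed (lowest adjusted p 0.988). Interferon-stimulated genes had a median of 0.16 with 22 of 27 higher (0.0527), and ribosomal protein genes 0.01 (36 higher, 33 lower, 0.962), where the mean (-0.04) and the test pointed down. Rescaled to equal sums that list had a median of -0.81 (0 higher, 69 lower, adjusted p 0.000156). Less the median of all loci it was -0.27. The sum of naive KO 1 (8331600 FPKM) came mostly from the Kif5c locus (7620000), so equal sums shrank that library most. With loci above 100000 FPKM left out of the sums, the list's median less that of all loci was 0.0148. Adjusted over the list alone, Txnip was higher among quiescence genes and Mcm2 among cell cycle genes.

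After 18 h of Th1 culture, the question was whether activated KO cells differ. Ide rose in KO cells again, as did Tmem181b-ps and the same unnamed locus beside Ide. Genes of the Th1 program, such as Il18r1, a receptor chain through which IL-18 drives Ifng, were lower by camera at the preset correlation. With an estimated correlation the list did not pass (adjusted p 0.538), and neither did Ifng or Tbx21 by themselves.

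Only 4 loci passed (all higher), and 452 had an unadjusted p below 0.05 against 809 expected. The count was 2 without any 1 of the 4 WT libraries or KO 2, and all loci moved by -0.32 when rescaled to equal sums. Ide was 28.6 ± 3.10 FPKM in WT and 53.5 ± 6.64 in KO, n = 4 each (log2 fold change 0.88, SE 0.13, adjusted p 0.0384). Its adjusted p rose above the threshold in 7 of 8 runs with a library left out, to 0.231 without KO 2. Tmem181b-ps was listed at 4.44, 5.02, 4.38 and 3.65 in KO and at 0, 0, 0.0155 and 0.0734 in WT (4.23e-06), and a second locus of that name also passed (0.0384). The unnamed locus was at 3.60, 3.65, 2.01 and 4.49 in KO and at 0, 0, 0.0314 and 0.0280 in WT (0.000226). Ifng was 13.6 ± 11.6 in WT and 7.02 ± 4.03 in KO (-0.76, adjusted p 1), Tbx21 5.07 ± 2.30 and 4.36 ± 0.748 (-0.08, 1), Ep300 17.9 ± 0.958 and 19 ± 0.615 (0.08, 1), and Il2 15.4 ± 3.84 and 17.8 ± 4.21 (0.21, 1).

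The Th1 program list had a median of -0.07 (14 of 21 lower, adjusted p 0.0177 at the preset correlation), and Il18r1 was lower when adjusted over the list alone. Mean log2 levels of that list overlapped between the genotypes (3.05 to 3.31 in WT, 2.85 to 3.15 in KO), and other splits of the libraries were not tried for it. With an estimated correlation 0 lists passed at 18 h (lowest adjusted p 0.538). Translation factors had a median of 0.09 (30 of 32 higher, 0.0471) and ribosomal protein genes also 0.09 (61 of 69 higher, 0.0523). The median of all loci at 18 h was itself 0.05. Lists of other genes matched on expression and transcript length had a median of 0.11, and the ribosomal protein list lay at percentile 25.1 of them. The match was loose, with a median log2 level of 9.69 for the list and 6.65 for the matched lists. With the estimated correlation the adjusted p was 0.771 for translation factors, whose median was -0.32 when rescaled to equal sums and which passed under none of the 4 other scalings (adjusted p 0.379 after median centring). Without 18 h WT 2, the median of the ribosomal protein list was -0.03. It passed without WT 1 (0.00479), WT 3 (0.00853), WT 4 (0.0172) or KO 4 (0.0274), at the preset correlation; with an estimated correlation and all libraries its adjusted p was 0.771.

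**Figure D3:**
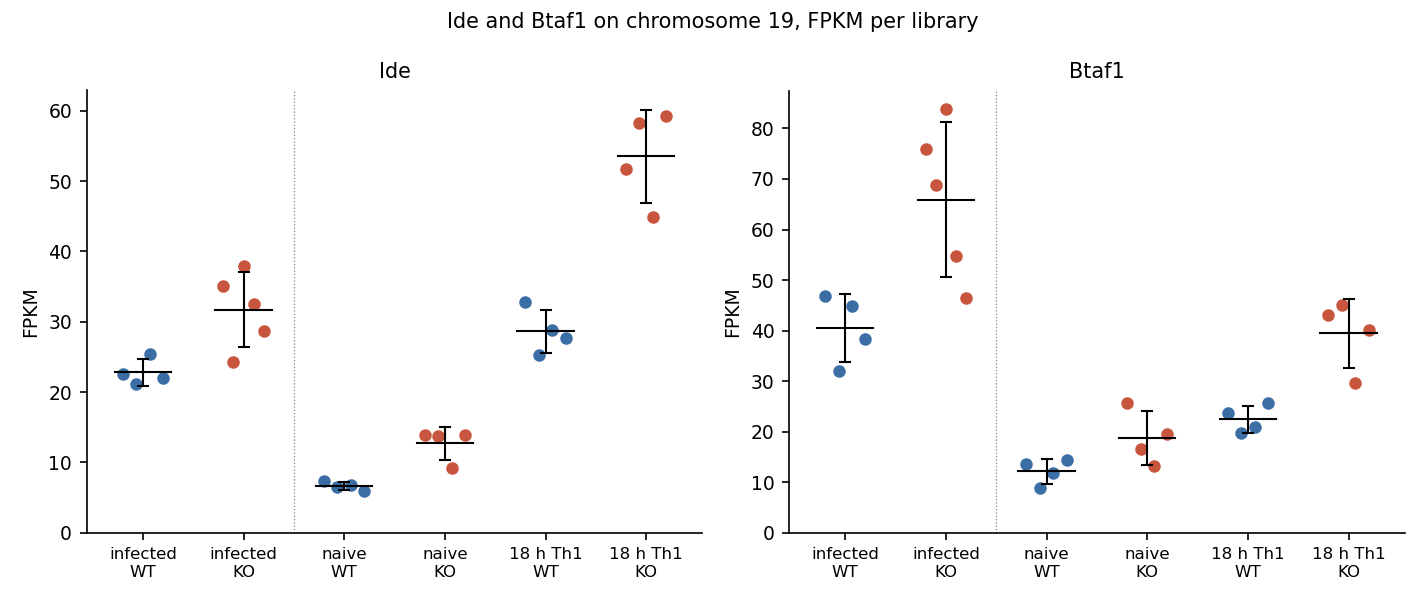
FPKM of Ide and Btaf1, which share a segment of chromosome 19, in each library with group mean and SD (infected, naive and 18 h cells, WT and KO). Ide passed the test in naive cells and at 18 h, from a mean of 6.63 to 12.7 and from 28.6 to 53.5.

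Stimulation itself remade the cells, and the question was what 18 h under Th1 conditions did in each genotype. Single metabolic genes that rose included Bcat1, which handles branched-chain amino acids, Cth of cysteine synthesis and the glycolytic enzyme gene Hk2. Transcription factors of effector cells (Irf4, Hivep3), the growth factor Il2 with its receptor Il2ra, and the checkpoint receptor Lag3 rose. Genes of early signalling (Fos, Fosb), the filament protein Vim and the quiescence gene Igfbp4 fell. Genes that build ribosomes rose in nearly all members of their list, and most translation factors rose.

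In WT, 8547 of 16185 loci passed (3382 higher, 5165 lower), or 5711 genes (2870 higher, 2841 lower), and in KO 8254 (3522 higher, 4732 lower), or 5624 genes (2980 higher, 2644 lower). The median of all loci was -0.20 in WT and -0.13 in KO. The split moved with the scale: 4420 higher and 3995 lower in WT after median centring, 4159 and 3953 after quantile normalization, and 1933 and 1502 when rescaled to equal sums, which moved all loci by 0.39. In KO that rescaling gave 2266 higher and 553 lower, with all loci moved by 0.56.

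Bcat1 went from 0.0431 ± 0.0174 to 45.2 ± 11.3 FPKM in WT (n = 4 each; log2 fold change 5.43, adjusted p 5.59e-12). Hivep3 rose from 3.12 ± 0.523 to 114 ± 7.52 (4.81, 8.61e-14) and Irf4 from 12.1 ± 1.84 to 353 ± 26.8 (4.77, 1.47e-12). Cdh11, an adhesion molecule, was listed at 0 in all naive WT libraries and at 38.8 to 104 at 18 h. Vim fell from 63.4 ± 4.04 to 1.20 ± 0.890 (-4.97), the ribosomal protein gene Rps15a from 2311 ± 499 to 92.8 ± 48.5 (-4.74), Fosb from 118 ± 12.5 to 3.50 ± 0.336 (-4.72), Fos by 4.47 and Arl4c, a small GTPase gene, by 3.98. Each gene was read from 1 locus, the tested one with the highest mean. A move of signal to another locus or, as for Rps15a, a near-identical copy would also appear as a fall, which was not tested. Il2 rose by 3.80 (1.09e-09) and Tbx21 by 2.12 (1.36e-05), Ep300 fell by 0.62 (2.35e-06), and Ifng did not pass (0.41, 0.584). In KO, Bcat1 (5.56), Irf4 (5.12), Hivep3 (4.78) and Tnfsf11, the cytokine RANKL (4.82), rose most, with Cth, which was listed at 0 in naive KO. There Vim (-5.05), Fosb (-4.44), Fos (-4.28), Arl4c (-4.13) and the Notch regulator Dtx1 (-3.94) fell most. Il2 rose by 3.98 in KO and Tbx21 by 2.24, Ep300 fell by 0.53, and Ifng did not pass (-0.04, 0.958). Ep300 in KO had 0.33 when rescaled to equal sums.

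Most lists moved together in WT. Ribosome biogenesis (median 1.66, 27 rose and 0 fell of 28, Gar1 from 11.9 ± 4.66 to 75.4 ± 15.5), amino acid and one-carbon genes (2.15, 20 rose, 1 fell), proteasome subunits (1.27, 30 rose, 1 fell, with Psmd7 up and Psmb10 down), mitochondrial ribosomal proteins (0.83, 42 rose, 1 fell, Mrps36 up and Mrpl9 down) and translation factors (0.93, 24 rose, 0 fell, with Eif5a) passed camera. So did activation genes (1.42, 20 rose, 5 fell). These 6 also passed with an estimated correlation, at adjusted p of 0.0153, 0.0153, 0.0233, 0.0414, 0.0414 and 0.0233.

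A further 8 lists passed camera at the preset correlation only. Oxidative phosphorylation (0.71, 40 rose, 2 fell; Ndufa12 up, Uqcrfs1 down) and cytokines (2.23, 12 rose, 3 fell; Ccl4 up, Il16 down) had estimated-correlation p of 0.102 each. Quiescence genes (-1.84, 2 rose, 16 fell; Bach2 up, Igfbp4 down) had 0.0514, follicular helper genes (0.75, 6 rose, 2 fell; Cd200 up, Sh2d1a down) 0.0518, cell cycle genes (0.69, 10 rose, 1 fell; Mcm3 up, Ccnd3 down) 0.0676 and glycolysis (0.75, 12 rose, 4 fell; Hk2 up, Pdk1 down) 0.0694. Interferon-stimulated genes (-0.95, 4 rose, 17 fell; Gbp2 up, Ddx58 down) had 0.284. T cell receptor signalling (-0.44, 4 rose, 14 fell; Zap70 up) had 0.334, and its median was 0.07 when rescaled to equal sums. Fry passed 20 of 21 lists.

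The other lists did not pass in WT. Ribosomal protein genes had 11 risen and 5 fallen of 69 (median 0.01, mean -0.02, adjusted p 0.101; Rps2 up, Rps15a down), and the Th1 program 8 and 8 (0.41, 0.125; Ccl4 up, Prf1 down). Regulatory T cell genes had 5 risen and 2 fallen (0.34, 0.0876; Il2ra up, Foxp3 down), co-inhibitory receptors 6 and 4 (0.32, 0.312; Lag3 up, Tox down) and described targets of miR-132 and miR-212 2 and 9 (-0.38, 0.113; Spry1 up, Itpkb down). Genes near the deleted locus had 6 and 8 (-0.03, 0.405, where the test pointed up) and monocyte markers 0 and 3 (-0.92, 0.176). Among lists too short to test, Gata3 fell and Ccr4 rose in the Th2 program. In KO the same 14 lists passed at the preset correlation (6 lists with an estimated correlation), and the ribosomal protein list as well (median 0.19, 17 rose, 3 fell, 0.00915; estimated correlation 0.573); a difference from WT was not called, since that list's interaction had a median of 0.11 and an adjusted p of 0.140.

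**Figure D4:**
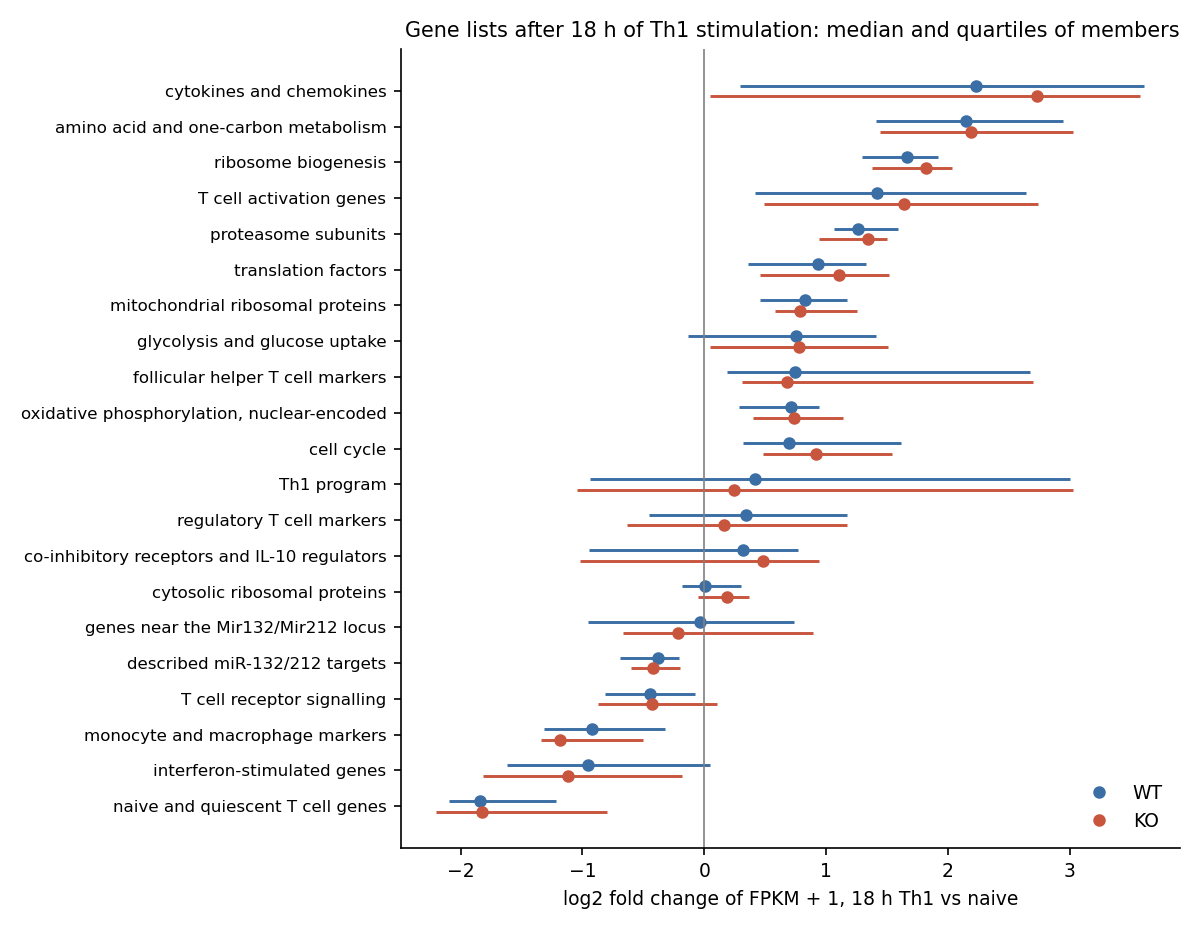
Median (points) and quartiles (lines) of log2 fold changes of FPKM + 1, 18 h against naive cells, for the 21 tested lists in WT and KO. Ribosome biogenesis had medians of 1.66 in WT and 1.82 in KO, and quiescence genes -1.84 and -1.82; T cell receptor signalling (-0.44 in WT) had 0.07 when rescaled to equal sums.

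The interaction asked whether the response to stimulation differed by genotype. The neutrophil-associated gene S100a8 was the 1 locus that passed, and it was listed in naive KO cells and not in naive WT cells. Interferon-stimulated genes such as Oasl2 and Zbp1, which sense or restrain viruses, were the 1 list that passed camera at the preset correlation. With an estimated correlation its adjusted p was 0.999, and under quantile normalization 0.0665. Limma called 1 of 16185 loci, with 677 at an unadjusted p below 0.05 against 809 expected. At 18 h S100a8 was listed at 0 in all KO libraries and at 0, 0, 2.02 and 3.04 in WT (adjusted p of the interaction 0.0390). That call was lost in 13 of 16 runs with 1 library left out, with an adjusted p of up to 0.138 without naive WT 1; it held without naive KO 4, 18 h WT 1 or 18 h WT 2. Ifng (-0.46, 0.988), Tbx21 (0.12, 0.991), Ep300 (0.09, 0.986) and Il2 (0.18, 0.988) did not pass. The list of interferon-stimulated genes had a median of -0.17, with 19 of 27 lower (adjusted p 0.0319, 0 alone), and 0.17 when rescaled to equal sums, which moved all loci by 0.23.

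Ide and Tmem181b-ps were called higher in both in vitro comparisons of genotype, where 0.000811 shared genes would be met by chance (Fisher's exact test, one-sided, p 1.23e-07). That expectation and p assume independent comparisons. Both effects came from 1 fit with a shared spread per gene (SE 0.131 for Ide in both), and the labels do not say whether both states shared animals. No gene name was shared with infected cells. There, however, 4 loci without a name passed on chromosome 17 between 6310547 and 6599736, the place of Tmem181b-ps, at the position of Dynlt1a, a dynein light chain gene. They were listed between 0 and 0.658 in WT and between 5.30 and 25.0 in KO (adjusted p 0.000111 to 0.00259), and were named after their values were seen. In infected cells Ide was 22.8 ± 1.88 in WT (n = 4) and 31.7 ± 5.34 in KO (n = 5; limma, 0.45, adjusted p 0.245). Across genes, which are not independent replicates, the fold changes of infected and naive cells had a Pearson r of 0.130 (Spearman 0.0412), infected and 18 h cells 0.143 (0.0633) and naive and 18 h cells 0.139 (0.0647). An r as large came from 3 of 35 splits of the libraries for infected and naive cells, with 0.159 as the highest of the others, and from 1 of 35, the real one, for each of the other pairs (highest others 0.11 and 0.10).

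A lost repressor would leave its targets higher. In infected cells, the 1270 genes with an 8mer or 7mer-m8 site lay 0.03 above the 4674 genes without a site, outside the range of -0.01 to 0.02 that held 95% of random lists (p 0.023). The 273 genes with an 8mer lay 0.07 above (0.0016). A difference as large came from 17 of 100 splits of the libraries for either site and from 8 of 100 for the 8mer. In naive cells the differences were 0.00 (0.51) and -0.02 (0.078), and at 18 h -0.01 (0.74) and 0.00 (0.39). Of the infected genes called higher, 4 of 21 with a UTR had a site (Rpl7l1, Rpp25l, Uba2 and Xpr1), or 19%, against 14.8% of the others (Fisher's exact test, two-sided, p 0.540). Within 5 Mb of the deleted locus, 1 of 165 loci was called in infected cells, where 0.880 were expected (Fisher's exact test, p 0.588). It was the locus named after Dph1 and Ovca2, which surrounds Mir132 and Mir212. Within that distance 0 loci were called in naive cells and at 18 h (p 1), where limma called 6 and 4 loci in all.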

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

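Outlying libraries were sought with Dixon's test in 232 groups of values at a level of 1 in 20, so that 12 are met by chance; 26 values stood out. The tests of a pseudogene shift, of the Trav stretch and of the chromosome 19 genes were chosen only after the results were seen, as were the last 2 sets of genes themselves.

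Cytosolic ribosomal protein genes had a median of 0.35 in infected KO against WT, which did not pass with an estimated correlation (adjusted p 0.589). A gain of short transcripts stays open. The list lay at percentile 100 of lists matched on length and expression, whose median was 0.13. Length was that of the longest annotated transcript of each gene, however, and the median log2 level was 7.64 for the list and 7.05 for the matched lists. A single library was excluded, since the lowest median with 1 left out was 0.26, without infected KO 2. That does not exclude 2 libraries together: KO 1 and KO 2 had mean log2 levels of 8.30 and 8.53. KO 3 to KO 5 (7.97 to 8.01) lay below WT 1 (8.26) and above WT 2 to WT 4 (7.73 to 7.87). A loss of reads from pseudogene copies was excluded as the whole cause, because 56 pseudogene loci had a median of 0.67. A smaller shift stays open, since reads of near-identical copies could not be assigned with certainty. The submitters' scaling stays open: less the median of all loci, the list had 0.11 under quantile normalization and 0.27 when rescaled to equal sums, against 0.35 as deposited. Its own median was -0.16 when rescaled to equal sums (25 higher, 48 lower), where all loci had a median of -0.42. Chance stays open as well, since 6 of 100 splits of the libraries gave a median as far from 0, with 0.43 as the highest of the others.

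Trav genes of the 353 kb stretch of chromosome 14 were near 0 in infected WT. Whether infected WT mice lacked the stretch stays open: 89.5% of its loci were higher in every KO than in every WT library, but its ends were drawn around the loci that passed, so this value could not have come out low. An effect of the KO allele that acts alike in naive and infected cells was excluded as the whole cause. The median share of the stretch in naive WT was 0.604 of that in naive KO (13.9% to 54.3% in naive WT). Such an effect predicts a share near 0, as in infected WT. An effect limited to infected cells was not tested, and a smaller effect stays open, since 18 h WT 3 had a share of 2.87%. Expression cannot separate a missing segment from silent genes.

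Ide, Btaf1 and Fgfbp3, which share a segment of chromosome 19, had higher values in KO in each comparison where they were tested (8 values, median 0.72). The copy number of a segment holding Ide and Fgfbp3 is known to vary among C57BL/6J mice, and the nearest genes outside the 3 had a median of 0.0654 (-0.26 to 0.66). Extra copies in KO mice nonetheless stay open, because March5, which lies between Btaf1 and Ide, had only 0.02, 0.18 and 0.24 in infected, naive and 18 h cells. Release from the microRNAs was excluded for the set, since 1 of the 3 has an 8mer or 7mer-m8 site (Btaf1, which did not pass in any comparison). No DNA was measured here.

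Chance was excluded for the counts in infected cells (1 of 100 splits called as many loci, which was the real one; 79 against 5 in the highest other) and for stimulation in WT (1 of 35; 8547 against 255) and KO (1 of 35; 8254 against 1). It was not excluded for naive cells (6 of 35; 6 against 22), 18 h cells (2 of 35; 4 against 4) or the interaction (27 of 100; 1 against 7). A split with several times the real count, as in naive cells, may point to structure among the libraries other than genotype, which was not tested. In infected cells the splits show only that the labelled groups differ. They cannot separate genotype from another difference between the 2 groups of mice. Of the 79 loci, 17 were the Trav loci, whose cause stays open. For the ribosomal protein list chance was not excluded in naive cells (33 of 35; 0.01 against 0.20) or at 18 h (35 of 35; 0.09 against 0.22). For genes with seed sites it was not excluded in infected (17 of 100; 0.03 against 0.05; 8mer alone 8 of 100, 0.07 against 0.09), naive (35 of 35; 0.00 against 0.08) or 18 h cells (32 of 35; -0.01 against 0.05). Loss of repression through sites was left undecided for genes called higher in infected KO (p 0.540).

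The library 18 h WT 2, the shallowest in vitro, stood far from the other 3 for many values. Its mean log2 level was 8.55 for ribosomal protein genes and 5.70 for ribosome biogenesis. Its FPKM were 28.4 for Bcat1, 313 for Irf4, 4.00 for Fosb, 1526 for Rps2, 6.73 for Mrpl9, 11.7 for Tox, 14.5 for Il16, 127 for Zap70, 17.5 for Spry1 and 14.3 for Itpkb. Infected WT 1 stood apart for translation factors (mean log2 level 6.44) and Il2 (142). Infected KO 4 stood apart for the Trav share (76.2%), infected KO 1 for Rpp25l (34.9) and infected KO 3 for Tnnt3 (0.955). Naive KO 4 stood apart for S100a8 (36.8), naive KO 3 for Ide (9.21), and naive KO 2 for Bcat1 (0.491) and Fosb (78.6). Naive WT 4 stood apart for Cth (0.157) and naive WT 2 for Mrpl9 (29.8). At 18 h, KO 4 stood apart for Ifng (1.23) and Ep300 (19.9), and WT 1 for Tbx21 (1.66).

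A difference of the KO effect between states passed for S100a8 (-4.79 on the log2 scale), a call lost in 13 of 16 runs with 1 library left out. It passed for the list of interferon-stimulated genes (median -0.17) at the preset correlation, with an adjusted p of 0.999 with an estimated correlation and a median of 0.17 when rescaled to equal sums.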

How the results depend on the processing

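The labels number the libraries in 1 run and name no animal or pair, so no pairing was part of the design. Paired by order of deposit within a genotype, naive and 18 h libraries had correlations of their deviations from the group means between -0.00822 and 0.0493, with 0 of 8 above 0.1, and 3 of 8 were highest for their own number, although the Trav shares of WT ranked alike by that order in both states. With that order as a replicate block, chosen after the data were seen, 8270 loci passed in WT, 7935 in KO and 0 in the interaction. Counts are called similar when within 1.5 times of the main one. Relative depth was lowest in infected KO 4 (0.629) and 18 h WT 2 (0.914), and its effect on genes with low values was not tested. Where a value below left its call or direction, the cause was not tested, except that stricter filters and left-out libraries leave fewer loci or samples.

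Infected cells, 79 loci: 7 of 10 alternatives gave a similar count, up to 104 loci, with 48 to 79 of the same loci; no filter gave 39 (36 higher, 3 lower), rescaling to equal sums 46 and that rescaling without the highest loci 38. With 1 library left out the count was 36 (without WT 2) to 74 (without WT 1). The ribosomal protein list (0.35) kept its call in 8 of 11; it had 0.35 with an estimated correlation (adjusted p 0.589), -0.16 rescaled to equal sums and 0.10 under quantile normalization. Left out 1 at a time, the libraries gave 0.26 to 0.44.

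Naive cells, 6 loci: 7 of 12 gave a similar count, with 2 (rescaled to equal sums) to 6 of the same loci; no filter gave 10, quantile normalization 16, library weights 2, leaving out the 3 libraries that stood apart 14 and a fit of 2 groups 1. Left-out libraries gave 4 (without KO 2) to 12 (without KO 3). The ribosomal protein list had -0.81 rescaled to equal sums (adjusted p 0.000156) and -0.05 to 0.04 with a library left out. Less the median of all loci it had -0.27 under that rescaling, and 0.0148 when loci above 100000 FPKM were left out of the sums.

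At 18 h, 4 loci: 4 of 12 gave a similar count. It was 2 with a pseudocount of 0.1, no filter, a stricter filter, median centring, 1 locus per gene, without the 3 libraries and in a fit of 2 groups, and 13 with library weights. Left-out libraries gave 2 (without any WT library or KO 2) to 3. The ribosomal protein list passed without a filter (0.0922, adjusted p 0.00578; with a filter and an estimated correlation 0.771), and had -0.0288 (without WT 2) to 0.152 (without WT 4) with a library left out.

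Stimulation in WT, 8547 loci: a stricter filter gave 5558 and rescaling to equal sums 3435, other alternatives up to 8959, left-out libraries 7998 to 8662. In KO, 8254: 2819 rescaled to equal sums, up to 9567 otherwise, 7473 to 7832 with a library left out. The rescaling without the highest loci gave 4570 higher and 3833 lower in WT, and moved all loci by -0.20 in infected cells, 0.23 in stimulated WT and -0.16 in the interaction. Median centring moved them by 0.20 and 0.12 and quantile normalization by 0.19 and 0.13 in WT and KO.

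Interaction, 1 locus: 0 with a pseudocount of 0.1, no filter, a stricter filter, either rescaling or without the 3 libraries, and 0 to 1 with a library left out. It was 0 in 12 of 16 such runs, as without naive WT 1. The 1 locus that passed without naive WT 2 was not S100a8, whose call was lost in that run.

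Values of named genes kept their call or lack of it in 4412 of 4697 cases, were weaker in 273 and turned in 12, all when rescaled to equal sums. Those 12 were Xist at 18 h against naive cells in WT (0.0694) and, in KO, Xist (0.62), Rps27 (0.23), Mrpl9 (0.19), Mrpl58 (0.37), Ndufv3 (0.0247), Uqcrfs1 (0.33), Il4ra (0.17), Slamf6 (0.31), Ltb (0.31), Slc38a2 (0.44) and Ep300 (0.33).

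Among lists that passed, checked under each scaling after the data were seen, quantile normalization kept 6 of 10 in infected cells, median centring 10 and the rescaling without the highest loci 5, with 2 changed in sign. T cell receptor signalling was lost after median centring in stimulated WT (adjusted p 0.0711) and KO (0.0749). The activation list of naive cells was lost when rescaled to equal sums (0.0743) or without the highest loci (0.0688), and the Th1 list at 18 h was kept throughout.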

Other observations

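Among infected KO cells, Skp1a, a part of a ubiquitin ligase, and Polr2f, a shared subunit of RNA polymerases, also passed the test as higher, as did Ncoa3, a transcription coactivator, and Abi1, which organizes actin. Their log2 fold changes were 1.01, 0.90, 1.07 and 0.97. Histone-handling genes Hat1 (0.57) and Rbbp4 (0.70), which act when new chromatin is assembled, passed as higher too. All of these were named after their values were seen.

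Xist, which marks cells with 2 X chromosomes, was high in every group: 162 ± 7.86 FPKM in infected WT (n = 4) and 151 ± 12.9 in infected KO (n = 5), 195 ± 19.2 and 175 ± 29.2 in naive WT and KO, and 141 ± 13.3 and 139 ± 13.5 at 18 h (n = 4 each). S100a8 in infected cells was listed at 18.9, 3.50, 11.4 and 39.0 in WT and at 3.39, 50.5, 38.9, 49.7 and 36.9 in KO.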
